A study of Homo sapiens with 18 samples.

How the data were processed

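RNA was sequenced from H1 human embryonic stem cells (an established cell line, also called WA01) and from H1 cells in which the zinc finger gene ZNF808 was knocked out, both differentiated towards pancreatic endocrine cells. The labels give 18 libraries in 6 groups of 3: wild type (WT) and knockout (KO) at stages S5, S6 and S7, the last stages of a protocol of 7. The labels do not say how the knockout was made, how many KO clones were used, or whether replicates of a group were separate cultures beyond a tag (E38, E39 or E44) that occurs once in each group. If the libraries of a group share a culture or a clone, the p-values measure the spread between these samples and not between independent differentiations or clones. Replicates are numbered 1 to 3 at S5 and S6 and 2 to 4 at S7, as the labels number them, and in each group they carry the tags in the order E38, E39, E44.

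Per the labels, the libraries were stranded and made from polyadenylated RNA. The authors' processing notes name STAR, RSEM and the human build hg19, with no versions and no settings. The deposited table holds raw counts per gene for 62480 genes, as whole numbers, with no normalization by the authors. Whether they are RSEM's expected counts after rounding, and how reads shared by several genes or lying on the opposite strand were counted, is not stated. Gene identifiers carry the suffix of a GENCODE annotation mapped back to GRCh37. The annotation at hand, GENCODE v29, is on GRCh38, so no coordinates are printed. It was used for chromosomes and for the order of genes along them, and 98.2% of the genes tested were found in it by identifier.

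Of the 62480 genes, 30005 had no count in any library. The filter filterByExpr (edgeR 4.0.16, minimum count 10, minimum total count 15, groups as given) kept 18883, which held at least 99.9% of the counts of every library. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit, robust) on the means of the 6 groups, with all 18 libraries sharing one estimate of the spread. This left 12 residual degrees of freedom, a median of 6.36 prior degrees of freedom and a common biological coefficient of variation of 0.144. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, two-sided. Levels are given in CPM (counts scaled to a common library size by TMM), as mean ± SD of 3 libraries. Fold changes are log2 values of the model, KO over WT or later over earlier stage, with a standard error (SE) computed from the fold change and its F statistic. Where a group had no count of a gene, the fold is a lower bound, set against 3 counts over the group. Where it had 1 to 3 counts, the ratio of summed counts scaled by library size is given with its 95% exact interval. Reads are not independent molecules, so bounds and intervals cover counting error only. One count corresponds to 0.0298 CPM in WT S5 replicate 1, and low levels rest on few counts.

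Contrasts were KO against WT at each stage, WT S6 against S5, WT S7 against S6, and the differences of the KO effect between stages (interaction), tested pairwise and together. The calls of the 3 stages were intersected by direction and set beside the overlap of independent lists. A total of 22 gene lists (398 genes, of which 352 were tested, 3 were absent from the table and 33 stood in at least 2 lists) covered beta cells, alpha cells, delta, gamma and epsilon cells, endocrine progenitors, endocrine secretory granules, pancreatic progenitors, pancreatic duct, acinar cells, hepatocytes, enterochromaffin cells, intestinal epithelium, stomach epithelium, mesenchyme, endothelium, neural cells, pluripotency, proliferation, endoplasmic reticulum stress, immediate early and heat shock genes, the mitochondrial genome, zinc finger genes around ZNF808 on 19q13.41, and genes of monogenic diabetes and pancreatic agenesis. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted over the 22 lists within a contrast. An estimated correlation and fry stand beside it, as do the members called over all genes tested and adjusted over the list alone. A list's direction rests on camera, which compares its members with all other genes. Of 22 medians over lists with a member without a count in a group, 9 changed when such members were set at their bound, and these 9 belong to lists that camera did not call.

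Lists, tests, contrasts, alternatives and the rule for named genes were chosen before the data were examined. The rule named ZNF808, INS, GCG, SST, PDX1, NKX6-1, NEUROG3, ALB, AFP and APOA1 in every KO comparison. It added the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a clone name. It further added the 3 members with the smallest p of each list that camera called or that had at least 3 called members. For the WT contrasts the numbers were 5, 5 and 2, for the interaction the 5 genes with the smallest p between S7 and S5. Genes on the Y chromosome were left out of the text. Genes behind counts of 5 or fewer are named too, whatever their place, as are a few others said to be chosen after their values were seen.

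The tag was checked as a pairing. For each tag, the deviations of its 2 libraries from their group means were correlated over 13522 genes. All were above 0.1 for KO against WT at S5 (0.216, 0.555 and 0.663 for E38, E39 and E44) and at S6 (0.275, 0.318 and 0.399), for WT S6 against S5 (0.103, 0.134 and 0.301) and for WT S7 against S6 (0.173, 0.209 and 0.107). At S7 the value of E38 was 0.035, so S7 was not treated as paired. The library most alike was not always that of the same tag. At S5 both E38 libraries resembled one of E39 most. For WT S6 against S5, the E38 libraries resembled those of E39 most and the reverse. For these tags the pairing is therefore uncertain there as well. With the tag as a block within stage, 6 residual degrees of freedom were left. Where the tags pair the libraries, blocked values stand beside the unblocked ones if the block changed the call of a named result or moved a count over 1.5 times. Blocked values that involve KO at S7 are given with the other alternatives only. Label draws that keep the pairs swapped genotypes within tags at S5 and S6 and freely at S7.

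Alternatives were DESeq2's size factors in edgeR, library totals only, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block (within stage, within genotype or over all libraries), fitting only the groups compared, a test against a 1.5-fold change (glmTreat), leaving out each library, the estimated inter-gene correlation and fry. Leaving out experiment E44, and camera on the interaction contrasts, were added after seeing the data. The pipeline was tested on simulated data: negative binomial counts with the pooled gene means, library sizes and gene-wise dispersions of the 18 libraries, in which genes of at least 5 CPM were changed 1.5-fold, 2-fold or 4-fold in KO at S5. edgeR recovered 64.2%, 92.5% and 98.5% of them, with 2.3% of its calls false. For a difference between stages the recovered shares were 20.9%, 70.1% and 98.5%. The simulated counts were drawn once from dispersions that edgeR estimated, with no effect of the tag. These shares therefore need not hold for the data. R 4.3.3 was used.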

Results

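Gene expression was measured by RNA sequencing in 18 libraries of H1 human embryonic stem cells on their way to pancreatic endocrine cells. Wild-type cells (WT) and cells with a knockout of ZNF808 (KO), which codes for a zinc finger protein of the KRAB family, were sampled at differentiation stages S5, S6 and S7, with 3 libraries per group. Total counts of replicates 1, 2 and 3 at S5 were 30394718, 40762092 and 27132406 in WT and 32124999, 42383768 and 30945054 in KO. At S6 they were 29744136, 38681119 and 28357497 in WT and 37780619, 37033459 and 30273728 in KO. At S7, replicates 2, 3 and 4 had 27401684, 30126058 and 31148896 counts in WT and 36273992, 29291585 and 26915307 in KO. The gene with the most counts in a library was CHGA (chromogranin A, of endocrine secretory granules) or GCG (glucagon). The 10 genes with the most counts in a library held between 8.54% and 18.7% of its counts. Transcripts of the mitochondrial genome held means of 0.794%, 2.27% and 3.82% of the counts in WT at S5, S6 and S7, and 0.849%, 2.55% and 4.86% in KO.

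ZNF808 (ENSG00000198482.14_8), the gene named in the genotype label, was still transcribed in KO. Its level was 3.7 ± 0.458 CPM in KO and 5.12 ± 0.37 CPM in WT at S5 (SD, n = 3 each, as for all levels that follow). At S6 the levels were 3.07 ± 0.741 and 4.48 ± 0.893 CPM, and at S7 3.87 ± 0.574 and 5.22 ± 0.542 CPM. The log2 fold changes of KO over WT were −0.47 (SE 0.197, adjusted p = 0.293), −0.55 (SE 0.2, adjusted p = 0.431) and −0.43 (SE 0.2, adjusted p = 0.543). None passed the test, which was adjusted over all genes. At each stage the KO library of a tag stood below the WT library of that tag (at S5 3.46, 3.42 and 4.23 against 4.77, 5.08 and 5.51 CPM). A transcript level alone does not show whether the protein was lost.

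Stage and genotype separated the libraries. On the 500 most variable genes, the first principal component held 81.3% of the variance and 99.8% of it lay between stages. The second held 8.74%, with 98.5% between stages. The third held 4.49%, with 99.7% between genotypes.

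WT S6 against S5 follows the course of differentiation in unedited cells. Hormone transcripts rose: GCG 19-fold from 1746 ± 314 to 33230 ± 4160 CPM (log2 4.25, SE 0.317, adjusted p = 2.9e-09), INS (insulin) 2.25-fold from 4580 ± 1690 to 10320 ± 957 CPM (adjusted p = 0.00516) and SST (somatostatin) 1.75-fold. IAPP, the islet amyloid polypeptide that beta cells secrete with insulin, rose from 0.314 ± 0.0892 to 1221 ± 28.3 CPM, the largest increase by the rule for named genes. NEUROG3, the transcription factor that starts endocrine differentiation, fell from 559 ± 11.6 to 39.9 ± 4.55 CPM, a 14.0-fold decrease. The pancreatic enzyme CELA3A fell from 48.8 ± 8.66 to 0.158 ± 0.0404 CPM, and APOA1 (apolipoprotein A-I) fell 13.2-fold.

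Among further large increases from S5 to S6 were ENTPD3, a surface enzyme of beta cells (log2 8.43), and WSCD2 (7.07). GNAT3, the taste G protein gustducin, had no count at S5 and was at least 418-fold higher at S6. PGR, the progesterone receptor, had 2 counts at S5 and 998 at S6, a ratio with a 95% interval of 147 to 4410. SOX10, a transcription factor of neural crest cells, and LRRC71 had no count at S6 and were at least 100-fold and 67.9-fold lower. TUBA4B and HSPB7 had 3 counts each at S6, with ratios between 0.00037 and 0.00526 and between 0.000645 and 0.00918. PDX1, a transcription factor of pancreatic progenitors and beta cells, rose (log2 0.32, adjusted p = 0.0116), while NKX6-1, another such factor, fell (log2 −0.52, adjusted p = 0.00024). AFP (alpha-fetoprotein) fell (log2 −0.94), and ALB (albumin) did not pass the test (log2 0.19, adjusted p = 0.737, 38 and 35 counts over the 3 libraries).

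Of 18883 genes tested, 10514 changed between S5 and S6 in WT (5084 higher and 5430 lower, 55.7% of genes). Camera called 11 of 22 lists, and 6 of them held with an estimated correlation. The beta cell list was higher (camera adjusted p = 8.76e-11), where 16 of 22 tested members rose and 4 fell. HOPX had a log2 fold change of 5.07 and PCSK1, the convertase that processes proinsulin, one of 3.15. In the secretory granule list 17 of 22 members rose and 1 fell, with CADPS at 1.39. Among endocrine progenitor genes 12 of 17 fell and 1 rose, with RGS16 at −2.58 and the Notch ligand DLL1 at −2.78. Among pancreatic progenitor genes 12 of 16 fell and 1 rose, with GATA4 at −1.65 and NR5A2 at −5.13. Of the acinar genes 12 of 14 fell, among them CELA3B (−7.68), and all 7 endothelial genes fell, among them TIE1 (−4.82) and CLDN5 (−2.77). These counts were the same adjusted over the list alone, except for 1 further granule gene that fell.

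The other 5 lists called between S5 and S6 did not hold with an estimated correlation. Alpha cell genes were higher as a list (9 of 16 rose and 5 fell, with LOXL4 at 4.56 and DPP4 at 4.77), at an adjusted p = 0.107 with an estimated correlation. Duct genes were lower (9 of 16 fell and 3 rose, with KRT19 at −2.46 and SLC4A4 at −3.77), at an adjusted p = 0.292. Neural genes were higher (11 of 16 rose and 5 fell, with ASCL1 at 2.96 and STMN2 at 1.8), at an adjusted p = 0.111, or 0.0374 with the replicate block. Their median and test were above 0 and their mean was below 0. Proliferation genes were lower (20 of 24 fell, 21 adjusted over the list alone, with MCM7 at −1.2 and MCM2 at −1.28), and all 13 transcripts of the mitochondrial genome rose (MT-ND3 2.32, MT-ND2 2.95), each list at an adjusted p = 0.598 with an estimated correlation. Medians of the 11 lists not called ran from −0.74 (intestinal epithelium, or −0.131 with members without counts at their bound) to 0.19 (endoplasmic reticulum stress). Median, mean and test differed in sign for delta, gamma and epsilon cells and for intestinal and stomach epithelium. Without WT S5 replicate 3, PDX1 had an adjusted p = 0.0549.

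WT S7 against S6 gives the last step of the course. TTR (transthyretin, made by alpha cells and hepatocytes) rose 7.41-fold to 33940 ± 1240 CPM, and GC, the vitamin D binding protein, rose 40.3-fold from 20.8 ± 3.52 to 836 ± 23.7 CPM. INS rose 1.86-fold to 19160 ± 2530 CPM (log2 0.89, SE 0.321, adjusted p = 0.0345), and GCG rose 1.64-fold to 54460 ± 18000 CPM (log2 0.71, SE 0.279, adjusted p = 0.0493). NEUROG3 fell a further 10.7-fold, and SST (log2 −1.12), PDX1 (−1.22) and NKX6-1 (−0.93) fell. LIN28A, an RNA-binding protein of early development, had no count at S7 and was at least 210-fold lower.

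Among the largest changes from S6 to S7, the increases were in UGT2A3 and APOH (1 and 2 counts at S6; ratios with 95% intervals of 154 to 34100 and 92.6 to 2780), CYS1 (log2 6.18), CD109 (6.13) and MAT1A (5.46). The decreases were in CRHBP, FGF19 and CEACAM6 (2, 3 and 3 counts at S7; ratios between 0.000601 and 0.0181, 0.00158 and 0.0226, and 0.00297 and 0.0428) and CHRNA1 (log2 −5.71). ALB (0.52, adjusted p = 0.36), AFP (−0.23, adjusted p = 0.541) and APOA1 (0.27, adjusted p = 0.216) did not pass the test.

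Between S6 and S7, 7646 genes changed in WT (3586 higher and 4060 lower, 40.5%). With library totals in place of TMM, the median log2 fold change of all genes was −0.185 in place of −0.042, and 2403 genes were higher and 5436 lower. Camera called 9 lists, and 3 held with an estimated correlation, all lower. Of the endocrine progenitor genes 13 of 17 fell and 1 rose, with RGS16 at −2.97 and SOX4 at −1.31. Of the pancreatic progenitor genes 7 of 16 fell, with GATA6 at −1.41. Of the pluripotency genes 7 of 10 fell and 1 rose, with LIN28B at −1.95 and TERF1 at −1.07.

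Called from S6 to S7 without holding were 6 lists. Alpha cell genes were higher (9 of 16 rose and 2 fell) at an adjusted p = 0.0545 with an estimated correlation, and hepatocyte genes were higher (12 of 29 rose and 5 fell, with VTN at 2.83) at an adjusted p = 0.0548. Transcripts of the mitochondrial genome were higher (8 of 13 rose, with MT-ND6 at 1.56 and MT-ND3 at 0.85) at an adjusted p = 0.495. Enterochromaffin genes were lower (7 of 12 fell, with TPH1, an enzyme of serotonin synthesis, at −1.71 and GCH1 at −0.82) at an adjusted p = 0.101. Neural genes were lower (9 of 16 fell and 2 rose, with TUBB3 at −1.97 and ASCL1 at −1.81) at an adjusted p = 0.0641, or 0.0422 with the block. Proliferation genes were lower (16 of 24 fell, with MCM2 at −0.82 and MCM7 at −0.61) at an adjusted p = 0.477. Adjusted over the list alone, 14 endocrine progenitor, 9 enterochromaffin, 10 neural and 19 proliferation genes fell, 10 alpha and 10 mitochondrial genes rose, and the counts of the other called lists were the same.

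Medians of the 13 lists not called from S6 to S7 ran from −2.1 (stomach epithelium) to 1.65 (intestinal epithelium, or 0.42 with members without counts at their bound). Median, mean and test differed in sign for delta, gamma and epsilon cells and for duct. With the block, GCG lost its call (log2 0.66, adjusted p = 0.0583), and the beta cell and stomach lists were lower (adjusted p = 0.024 and 0.0223, or 0.43 and 0.213 with an estimated correlation). Each of 5 left-out libraries ended the calls of INS (adjusted p up to 0.103 without WT S7 replicate 2) and GCG (up to 0.268 without WT S7 replicate 3).

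**Figure D1:**
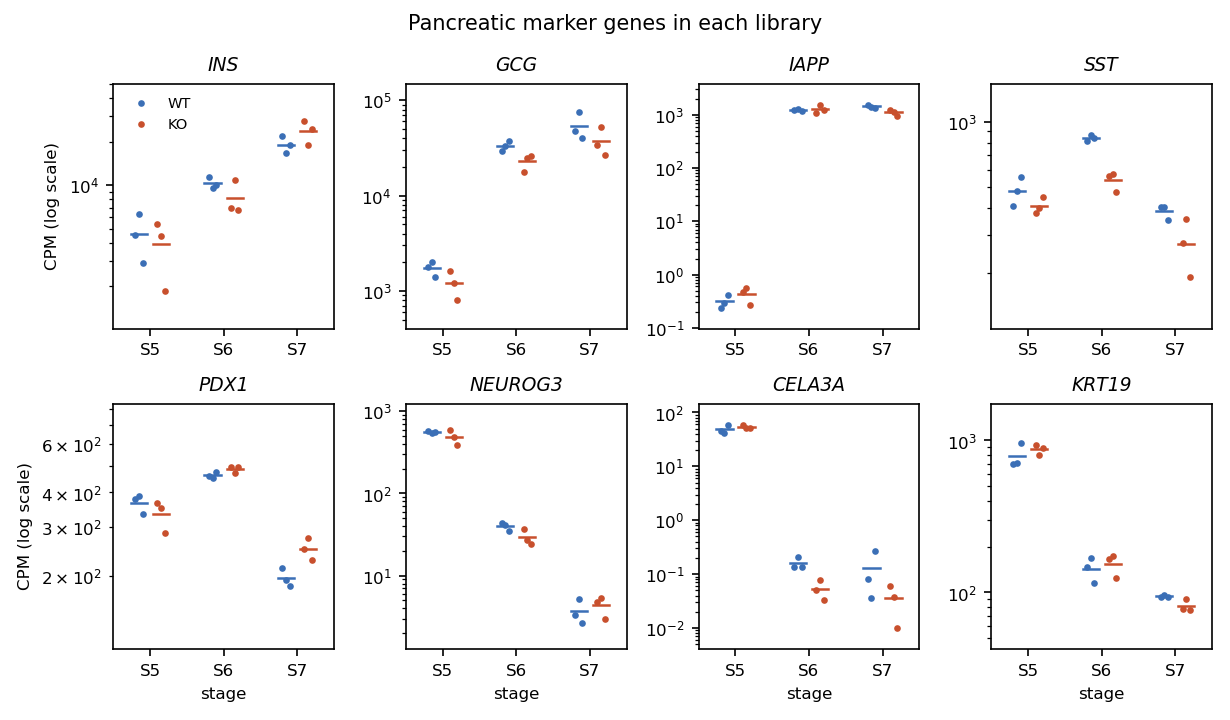
Levels in CPM (log axis) of INS, GCG, IAPP, SST, PDX1, NEUROG3, CELA3A and KRT19 at S5, S6 and S7, with a point per library (WT blue, KO red, 3 libraries per group) and a bar at the mean of each group. GCG in WT rises from a mean of 1746 at S5 to 54460 CPM at S7, and NEUROG3 falls from 559 to 3.73 CPM.

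KO against WT at S5 asks what the knockout of ZNF808 goes with at the earliest stage sampled. A set of genes was nearly silent in KO: DYNLT3 (ENSG00000165169.11_6), a dynein light chain, stood at 0.195 ± 0.0449 CPM in KO and 29.9 ± 2.78 CPM in WT (150-fold lower, log2 −7.23, SE 0.19, adjusted p = 1.16e-14). TRIM4, a RING finger protein (0.358 ± 0.153 against 24.96 ± 0.798 CPM), and ARMCX1, a protein of the mitochondrial outer membrane (0.364 ± 0.0822 against 30.5 ± 1.62 CPM), were similarly low. CAT, the catalase that breaks down hydrogen peroxide, was 6.96-fold higher (53.1 ± 7.49 against 7.61 ± 0.717 CPM, log2 2.8, SE 0.119, adjusted p = 1.73e-11). OAS3, an enzyme induced by interferon, stood at 18.3 ± 8.64 CPM in KO and 1.45 ± 0.0732 CPM in WT (log2 3.65, adjusted p = 3.56e-07). ARX, the transcription factor that sets alpha cell identity, was lower (52.1 ± 1.87 against 86.5 ± 2.21 CPM, log2 −0.73, adjusted p = 0.000996), and AFP was higher (25.2 ± 4.19 against 6.59 ± 1.23 CPM, log2 1.93, adjusted p = 0.000281).

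The other largest increases at S5 were in GPRC5D-AS1 (log2 3.83), FAM66B (2.94), GLIPR1 (2.91), PCDHA6 (2.79), a clustered protocadherin, and ZNF502 (2.49). The other largest decreases were in ZBED6CL (−6.45, 4 counts in KO), IQCA1 (−6.32) and LRRC61 (−6.29). LINC00865 had no count in KO and was at least 105-fold lower, and ZNF441 had 2 counts in KO and 386 in WT (95% interval of the ratio 0.000584 to 0.0176). PCDHA6 shares exons with its gene cluster, FAM66B and the zinc finger genes have close relatives, and GPRC5D-AS1 overlaps a gene of the opposite strand, so their counts depend on how shared reads were assigned. While ARX, PAX6 and ONECUT2 were called, these hormones and transcription factors did not pass the test: INS log2 −0.23 (adjusted p = 0.822; 3908 ± 1840 against 4580 ± 1690 CPM), GCG −0.53 (0.423), SST −0.23 (0.57), PDX1 −0.14 (0.603), NKX6-1 −0.14 (0.583) and NEUROG3 −0.2 (0.736). Nor did ALB (0.91, adjusted p = 0.357) or APOA1 (0.34, 0.361). Without WT S5 replicate 2 or KO S5 replicate 3, the log2 fold change of INS was 0.07 or 0.11.

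Camera called 11 lists at S5, 5 lower and 6 higher, and none held with an estimated correlation. Fry called 8 of these 11, 5 lower and 3 higher. In the alpha cell list ARX fell, and adjusted over the list alone ARX, IRX1 and IRX2 fell and GC rose, of 16 tested members (adjusted p = 0.0127, or 0.178 with an estimated correlation). Among 17 endocrine progenitor genes CBFA2T2 fell (log2 −0.41), and RUNX1T1 fell as well over the list alone (adjusted p = 0.0288, or 0.078 with an estimated correlation). Among 22 secretory granule genes CADPS (−0.42) and PTPRN2 (−0.4), both of dense-core vesicles, fell, and PTPRN, STXBP1 and SYT7 fell as well over the list alone (adjusted p = 0.00091, or 0.078 with an estimated correlation). Among 16 neural genes SYT1 (−1.39), a calcium sensor of vesicle release, and NRXN1 (−0.56) fell (adjusted p = 0.0021, or 0.078 with an estimated correlation). Among 30 genes of monogenic diabetes and pancreatic agenesis PAX6 (−0.49), an islet transcription factor, and PPP1R15B (−0.59) fell (adjusted p = 0.0117, or 0.078 with an estimated correlation).

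Of the higher lists at S5, that of hepatocytes had AFP, TM4SF5 (log2 2.62) and FGG (1.17), a chain of fibrinogen, up among 29 tested members (adjusted p = 0.0021, or 0.078 with an estimated correlation). In the duct list ANXA4 (0.52) and TFF1 (1.54) rose and ONECUT2 (−0.83) fell, of 16 (adjusted p = 0.018, or 0.28 with an estimated correlation). In the stomach list TFF1 rose, and CTSE (1.77) as well over the list alone, of 10 (adjusted p = 0.00371, or 0.078 with an estimated correlation). In the mesenchyme list ACTA2 (1.45), the smooth muscle actin, rose, and over the list alone also POSTN, on 21 counts in KO and 3 in WT, of 20 (adjusted p = 0.00435, or 0.28 with an estimated correlation). No member of the proliferation list was called, but 24 of 24 were above 0 (median 0.33, with AURKA at 0.47, CCNB1 at 0.37 and TYMS at 0.57) at an adjusted p = 0.000209, or 0.392 with an estimated correlation. No member of the pluripotency list was called either, and 10 of 10 were above 0 (median 0.25, with L1TD1 at 0.86 and LIN28A at 0.48) at an adjusted p = 0.0171, or 0.078 with an estimated correlation. Counts adjusted over the list alone were otherwise those over all genes.

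The 11 lists not called at S5 had medians of −0.13 (beta cell, where PAX6 fell), −0.26 (delta, gamma and epsilon cells), −0.06 (pancreatic progenitors, where ONECUT2 fell), 0.12 (acinar), 0.02 (enterochromaffin, where CXCL14 rose, log2 1.99), 0.34 (intestinal epithelium, where TFF3 rose, 0.56), 0.16 (endothelium), 0.03 (endoplasmic reticulum stress), 0.07 (immediate early and heat shock), 0.11 (mitochondrial genome) and 0.05 (zinc finger genes around ZNF808, where ZNF528, 1.41, and ZNF702P, 0.74, rose). For pancreatic progenitors, mean and median differed in sign.

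At S5, 351 genes changed (144 higher and 207 lower, 127 of them over 2-fold). With the replicate block, 1402 genes were called (572 higher and 830 lower), which included all 351; fitting only the 6 libraries of S5 gave 72 and DESeq2 gave 616. The block added calls for GCG (log2 −0.57, adjusted p = 0.00821), IRX2 (0.00368), IRX1 (0.0218), RUNX1T1 (0.0155), RFX6 (0.0199), STXBP1 (0.0109), HNF4A (0.0358) and DCX (0.0364), all lower, and for CTSE (0.000606), CLDN18 (2.4e-05), SPARC (0.0327), L1TD1 (0.0188), AURKA (0.00858), CCNB1 (0.0202) and TYMS (0.00905), all higher. It also called the beta cell list lower (adjusted p = 0.00238, or 0.219 with an estimated correlation) and the immediate early and heat shock list higher (0.0311, or 0.295). The count was 153 without WT replicate 1, 177 without WT replicate 2 and 541 without KO replicate 3 (273 of the 351 kept). Of 31 named genes called, 20 kept their call whichever library was left out; TFF1 (adjusted p up to 0.21), FGG (0.194), ACTA2 (0.184), ONECUT2 (0.181), TM4SF5 (0.146), PAX6 (0.132), PTPRN2 (0.132), ANXA4 (0.125), NRXN1 (0.0967), CBFA2T2 (0.0847) and CADPS (0.0534) did not, and without KO replicate 3 the calls of the duct (adjusted p = 0.303), pluripotency (0.0628), endocrine progenitor (0.241), alpha (0.0942), mesenchyme (0.0939) and monogenic diabetes (0.0928) lists ended.

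KO against WT at S6 puts the same question a stage later. DYNLT3 (0.485 ± 0.0891 against 55.0 ± 1.11 CPM, log2 −6.83), TRIM4 (−7.53) and ARMCX1 (−7.04) were again nearly silent in KO, and CAT was again higher (115 ± 11.9 against 17.3 ± 0.477 CPM, log2 2.73, SE 0.115, adjusted p = 1.19e-11). GHRL, the hormone ghrelin of epsilon cells, stood at 9.75 ± 0.868 CPM in KO and 23.7 ± 6.53 CPM in WT (log2 −1.28, SE 0.209, adjusted p = 0.00281), and ARX was lower (log2 −0.55, SE 0.108, adjusted p = 0.0127). INS (−0.33, adjusted p = 1; 8188 ± 2320 against 10320 ± 957 CPM), GCG (−0.54, 0.902; 22940 ± 4560 against 33230 ± 4160 CPM) and SST (−0.65, 0.0742; 536 ± 54.5 against 840 ± 27.5 CPM) did not pass the test.

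The other largest increases at S6 were in GPRC5D-AS1 (log2 4.11), ZNF630 (3.65), COL11A2, a collagen chain (3.49), PCDHA6 (3.48), FAM66B (3.2) and the long noncoding RNA PURPL (2.26). The other largest decreases were in LINC00865 (−7.16, 4 counts in KO) and IQCA1 (−6.22, 5 counts in KO). ZNF441, ZBED6CL and ZXDA had 1 count each in KO against 538, 510 and 311 in WT, with ratios between 4.24e-05 and 0.00939, 4.47e-05 and 0.0099, and 7.32e-05 and 0.0163. PDX1 (0.08, adjusted p = 1), NKX6-1 (0.18, 0.976), NEUROG3 (−0.42, 0.837), ALB (0.87, 0.811), AFP (0.02, 1) and APOA1 (0.5, 0.318) did not pass the test.

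Camera called 4 lists at S6, and 2 held with an estimated correlation. The delta, gamma and epsilon cell list was lower: of 11 tested members GHRL fell, and adjusted over the list alone SST and HHEX (log2 −0.77), a delta cell transcription factor, fell as well (adjusted p = 6.05e-05, or 0.0201 with an estimated correlation). The list of enterochromaffin cells, the serotonin-producing cells of the gut, was higher. Its 12 members were all above 0 (median 0.34, with LMX1A at 0.5, CXCL14 at 1.17 and DDC at 0.35), none was called over all genes, and 7 rose adjusted over the list alone (adjusted p = 9.01e-08, or 0.0456 with an estimated correlation). The alpha cell list was lower without holding: of 16 members ARX fell, and over the list alone 4 fell while TM4SF4 (1.11) and POU3F4 (0.94) rose (adjusted p = 0.0141, or 0.272 with an estimated correlation). The hepatocyte list was higher without holding: of 29 members TM4SF5 (2.09) rose, and over the list alone 6 rose, among them AMBP (0.43) and APOM (0.71) (adjusted p = 0.0049, or 0.132 with an estimated correlation).

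Of 31 tested zinc finger genes around ZNF808, ZNF528 (log2 1.62, adjusted p = 0.000778), ZNF702P (0.86, 0.0272) and ZNF331 (0.57, 0.0164) rose at S6, and the list was not called (median 0.06, adjusted p = 0.0568). In the duct list the chloride channel CFTR rose (1.57), and in that of monogenic diabetes PPP1R15B fell (−0.44). Medians of the 18 lists not called ran from −0.37 (endothelium) to 0.21 (intestinal epithelium, or 0.111 with members without counts at their bound). Median, mean and test differed in sign for beta cells, pancreatic progenitors, stomach, mesenchyme, neural and monogenic diabetes.

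At S6, 195 genes changed (116 higher and 79 lower, 102 of them over 2-fold). With the replicate block, 501 were called (258 higher and 243 lower), which included 193 of the 195. The block added calls for SST (log2 −0.65, adjusted p = 0.00253), GCG (−0.55, 0.0153), NEUROG3 (0.0446), IRX1 (0.00684) and HHEX (0.0168), all lower, and for LMX1A (0.000374), CXCL14 (8.96e-05), DDC (0.00627), AMBP (0.0365) and TM4SF4 (1.62e-05), all higher. It also called higher the duct (adjusted p = 0.0271), intestinal (0.0459), mitochondrial (0.0265) and zinc finger (0.0271) lists and lower the endoplasmic reticulum stress list (0.0206); with an estimated correlation their adjusted p were between 0.239 and 0.75. The count was 110 without WT replicate 2, 128 without KO replicate 1 and 120 without KO replicate 3. Single left-out libraries ended the calls of TM4SF5 (adjusted p up to 0.287), ZNF702P (0.208), ZNF331 (0.138), ARX (0.105) and, without KO replicate 1, the alpha list (0.162).

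KO against WT at S7 compares the last stage. Genes of alpha, delta, gamma and epsilon cells were lower: GHRL stood at 8.2 ± 2.69 CPM in KO and 22.9 ± 1.03 CPM in WT (log2 −1.47, SE 0.215, adjusted p = 0.000766), ARX at 80.8 ± 8.67 and 132 ± 20.7 CPM (−0.71, SE 0.109, adjusted p = 0.000927), and LOXL4, an alpha cell marker, at 204 ± 18.7 and 330 ± 5.59 CPM (−0.7, SE 0.116, adjusted p = 0.00211). Genes of enterochromaffin cells were higher, among them SLC18A1, the vesicular monoamine transporter (37.4 ± 3.96 against 24.9 ± 0.255 CPM, 0.58, adjusted p = 0.00311), and LMX1A, a transcription factor of these cells (0.61, adjusted p = 0.0164). APOA1 was 2.24-fold higher (51.1 ± 6.36 against 22.8 ± 1.68 CPM, log2 1.17, SE 0.169, adjusted p = 0.000619). DYNLT3 (0.335 ± 0.156 against 59.7 ± 2.23 CPM, log2 −7.44), TRIM4 (−7.4) and ARMCX1 (−6.73) were nearly silent, and CAT was 7.22-fold higher (167 ± 13 against 23.2 ± 1.86 CPM, log2 2.85, adjusted p = 5.72e-12). INS (0.31, adjusted p = 1; 23780 ± 4340 against 19160 ± 2530 CPM) and GCG (−0.53, 0.671; 37810 ± 13200 against 54460 ± 18000 CPM) did not pass the test.

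The other largest increases at S7 were in PON3, a paraoxonase (log2 4.04), PCDHA6 (4.02), ZNF630 (3.66), GPRC5D-AS1 (3.22), FAM66B (3.19) and the histone gene H2AC13 (2.74), whose relatives are alike in sequence. The other largest decreases were in LRRC61 (−6.81), in LINC00865, with no count in KO (at least 167-fold lower), in ZNF441 and ZXDA, with 1 count each in KO (ratios between 3.58e-05 and 0.00792 and between 7.81e-05 and 0.0174), and in ACTR3C, with 2 (between 0.0014 and 0.0428). PDX1 (0.35, adjusted p = 0.133), NKX6-1 (0.3, 0.241), SST (−0.5, 0.219), NEUROG3 (0.23, 1), ALB (0.09, 1) and AFP (−0.17, 1) did not pass the test.

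Camera called 8 lists at S7, and 4 held with an estimated correlation. In the alpha cell list ARX, LOXL4, IRX1 (log2 −0.52) and IRX2 (−0.52) fell, of 16 tested members, and over the list alone GC fell as well while TM4SF4 (0.95) and POU3F4 (0.99) rose (median −0.36, adjusted p = 9.21e-06, or 0.0363 with an estimated correlation). In the delta, gamma and epsilon list GHRL and ACSL1 (−0.45) fell, of 11, and adjusted over the list alone 7 fell and BCHE (0.65) rose, with CRH at −1.09 (median −0.45, adjusted p = 9.61e-07, or 0.00627 with an estimated correlation). In the enterochromaffin list SLC18A1, LMX1A, DDC (0.4), which makes serotonin from its precursor, and CXCL14 (1.58) rose, and 10 rose over the list alone. Its 12 members were all above 0 (median 0.5, adjusted p = 2.21e-13, or 0.00627 with an estimated correlation), and 3 of them (FEV, CHGA and MNX1) stand in another list as well. In the hepatocyte list APOA1, AMBP (0.77), F2 (0.55, prothrombin), APOC3 (0.62) and TM4SF5 (2.19) rose and AGT (−0.68, angiotensinogen) fell, of 29, and over the list alone 9 rose and 1 fell (adjusted p = 0.000308, or 0.04 with an estimated correlation).

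The other 4 lists called at S7 did not hold with an estimated correlation. Beta cell genes were higher, with 19 of 22 above 0. DLK1 (log2 0.52) rose, and over the list alone MAFA, SIX2, PDX1, NKX6-1 and DLK1 rose and IAPP (−0.38) fell (adjusted p = 9.62e-05, or 0.231 with an estimated correlation). Proliferation genes were lower, with none called and 0 of 24 above 0 (median −0.43, with CENPF at −0.58, MCM3 at −0.52 and UBE2C at −0.65, adjusted p = 1.05e-07, or 0.399 with an estimated correlation). Transcripts of the mitochondrial genome were higher, with none called and 13 of 13 above 0 (median 0.4, with MT-ATP6 at 0.54, MT-ATP8 at 0.48 and MT-CO2 at 0.48, adjusted p = 0.0418, or 0.704 with an estimated correlation). Intestinal genes were higher, with none called and 11 of 13 above 0 (median 0.3, with CDX2 at 1.11, CDH17 at 1.1 and FABP1 at 1.92, adjusted p = 0.0418, or 0.231 with an estimated correlation). Medians of the 14 lists not called ran from −0.31 (mesenchyme) to 0.17 (neural, where SYT1 fell, −1.39, or 0.07 with members without counts at their bound). Median, mean and test differed in sign for pluripotency and endoplasmic reticulum stress. In lists not called, PAX4 (0.58), a transcription factor of beta cell precursors, ZNF528 (2.04) and ZNF331 (0.51) rose.

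At S7, 252 genes changed (137 higher and 115 lower, 125 of them over 2-fold). The count was 143 without WT replicate 4, 144 without KO replicate 2, 163 without KO replicate 3 and 424 with DESeq2. Single left-out libraries ended the calls of F2 (adjusted p up to 0.162), IRX1 (0.159), CXCL14 (0.157), DLK1 (0.13), ACSL1 (0.127) and LMX1A (0.0891), of the intestinal list (0.0564 without WT replicate 3, 0.241 without WT replicate 4, 0.137 without KO replicate 3) and of the mitochondrial list (0.139, 0.366, 0.0832 and 0.261 without WT replicates 3 and 4 and KO replicates 2 and 3).

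**Figure D2:**
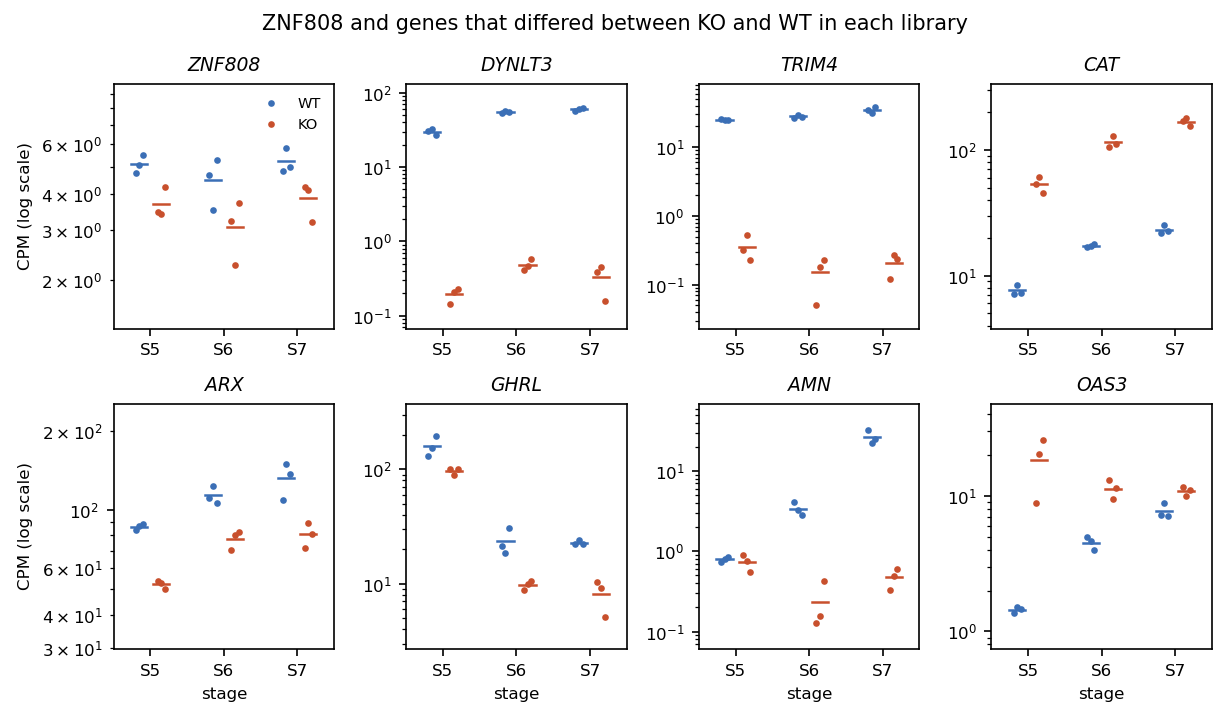
Levels in CPM (log axis) of ZNF808, DYNLT3, TRIM4, CAT, ARX, GHRL, AMN and OAS3 at S5, S6 and S7, with a point per library (WT blue, KO red, 3 libraries per group) and a bar at the mean of each group. DYNLT3 has KO means between 0.195 and 0.485 CPM and WT means between 29.9 and 59.7 CPM, while for ZNF808 the KO means lie between 3.07 and 3.87 CPM and the WT means between 4.48 and 5.22 CPM.

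**Figure D3:**
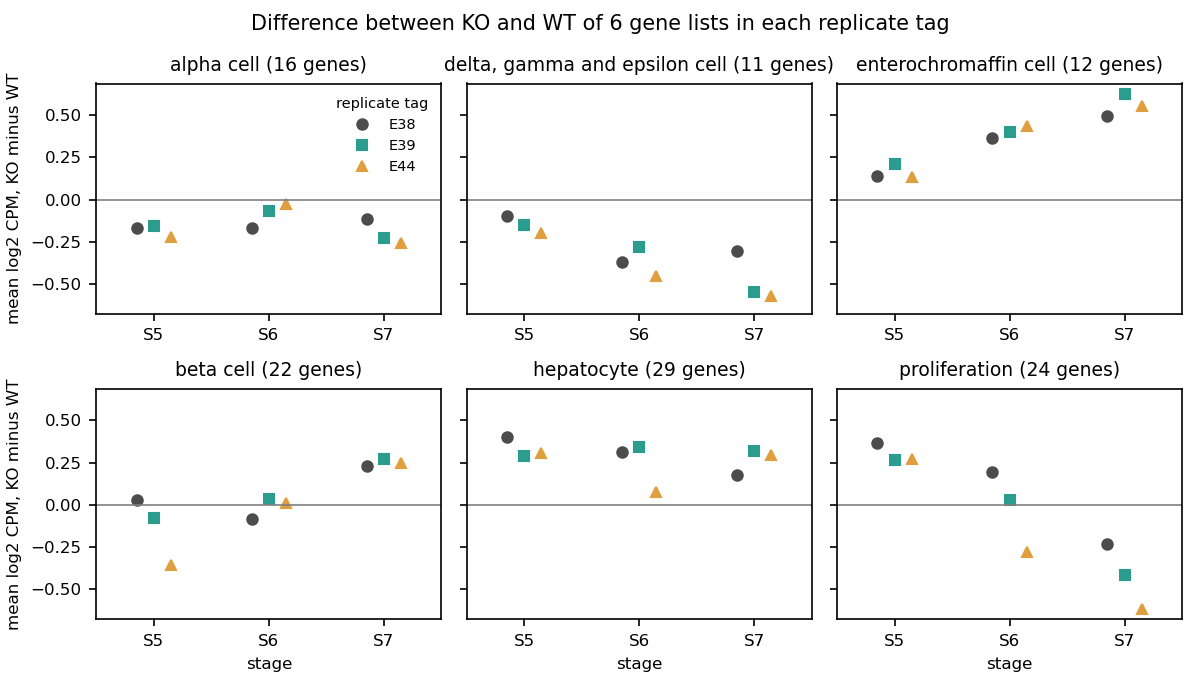
Mean log2 CPM in KO minus WT over the tested members of 6 gene lists (alpha 16, delta, gamma and epsilon 11, enterochromaffin 12, beta 22, hepatocyte 29 and proliferation 24 genes) at S5, S6 and S7, with a point per experiment tag (E38, E39, E44). The enterochromaffin points at S6 lie between 0.363 and 0.438, all above 0.

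The overlap of the calls asks whether the same genes changed at each stage. Of 539 genes called at any stage, 89 were called in the same direction at all 3 stages (45 higher and 44 lower in KO; independent lists would share 0.00642 and 0.00527). They include DYNLT3, TRIM4, ARMCX1, ZNF441 and ARX among the lower and CAT, PCDHA6, ZNF528, ZNF630 and FAM66B among the higher. A further 81 genes were called at exactly 2 stages and 369 at 1. S5 and S6 shared 117 genes in the same direction (63 higher, 54 lower; 0.885 and 0.866 for independent lists), S6 and S7 131 (72 and 59; 0.842 and 0.481), and S5 and S7 98 (49 and 49; 1.04 and 1.26). KCNJ8 and THSD4 were called in opposite directions, lower at S5 and higher at S6. With the replicate block S5 and S6 shared 235, and fitting only the groups compared gave 54, with 44 at all 3 stages. Without WT S6 replicate 2, S5 and S6 shared 74 and S6 and S7 85.

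Among the 89 genes, ADIPOR1, ETNK2 and RBBP5 lie on chromosome 1 (order of GENCODE v29 on GRCh38). They stand within a run of 39 neighbouring genes, from LAD1 to NUAK2, most of them lower in KO. The median log2 fold change of the run was −0.45 at S5, −0.32 at S6 and −0.37 at S7. Of the 39 genes, 35 were below 0 at S6 and at S7. Only genes with a mean of at least 5 CPM were scanned. The ends come from a median over 21 genes and are not sharp. LAD1 had log2 fold changes of 0.043, 0.078 and 0.135 at S5, S6 and S7, and NUAK2 had 0.669 at S5. Outside the run, KIF21B had −0.76, −0.718 and −0.544. ADIPOR1, an adiponectin receptor, stood at 95.9 ± 4.75 CPM in KO and 135 ± 2.22 CPM in WT at S5 (log2 −0.5, SE 0.0746, adjusted p = 0.00107). PPP1R15B, called at S5 and S6, lies in the run as well. The run was chosen after the values were seen.

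**Figure D4:**
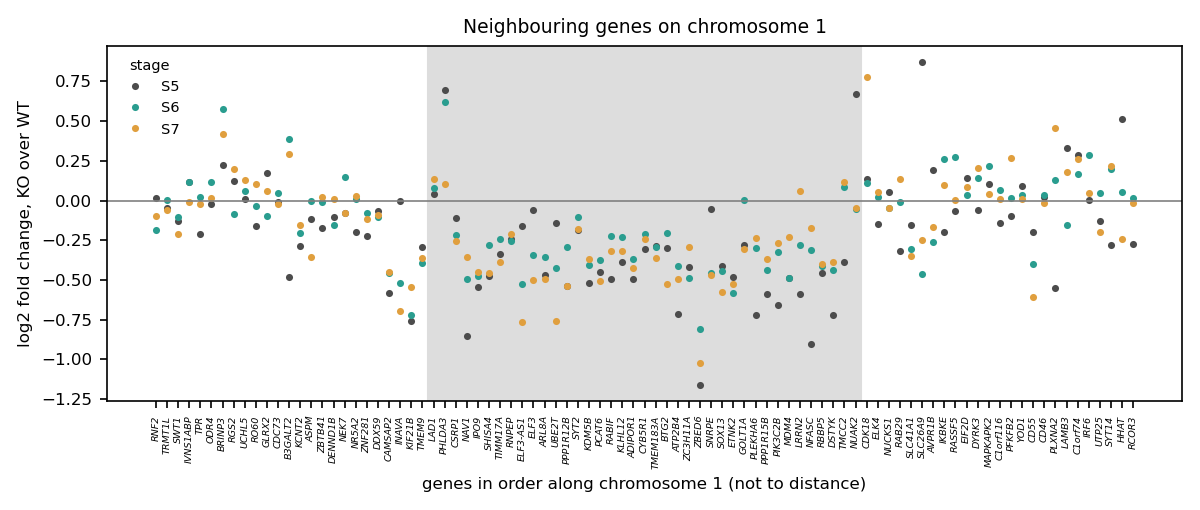
Log2 fold change of KO over WT of neighbouring genes of chromosome 1 (mean of at least 5 CPM), in gene order and not to distance. There is a point per gene at S5, S6 and S7. The 39 genes of the shaded run from LAD1 to NUAK2 have medians of −0.45, −0.32 and −0.37 at the 3 stages.

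The interaction asks whether the KO effect differs between stages. AMN, amnionless, a membrane protein of vitamin B uptake, rose in WT from 0.803 ± 0.0583 CPM at S5 to 3.41 ± 0.66 at S6 and 26.6 ± 5.28 at S7, while in KO it stood at 0.737 ± 0.169, 0.235 ± 0.162 and 0.473 ± 0.134 CPM. Its log2 KO effect at S7 differed from that at S5 by −5.72 (SE 0.422, adjusted p = 1e-06). OAS3 (−3.16, SE 0.385, adjusted p = 0.00161) and OAS1 (−2.33, SE 0.373, adjusted p = 0.0265), both induced by interferon, had a KO effect that was larger at S5 than at S7; for OAS3 it was 3.65 at S5, 1.32 at S6 and 0.49 at S7. The ion channel gene ASIC2 (1.21, adjusted p = 0.0148) and the neural and endocrine transcription factor MYT1 (0.86, adjusted p = 0.0265) were lower in KO at S5, with log2 fold changes of 0.47 and 0.4 at S7. AFP differed by −2.1 (adjusted p = 0.0346).

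Between S7 and S5 the KO effect differed for 42 genes (21 in each direction) and between S6 and S5 for 5: SPTB (1.07), KCNJ8 (1.31) and THSD4 (0.93) upwards, OAS3 (−2.33) and AMN (−3.8) downwards. Between S7 and S6 edgeR called 0 genes, limma-voom 0 and DESeq2 2. In edgeR 496 of 18883 genes had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. With the replicate block, 123 genes were called between S6 and S5. The joint test called 5: SPTB, ASIC2, OAS3, KCNJ8 and AMN. Left-out libraries moved both counts of 5 (the joint one to values between 2 and 15, that between S6 and S5 to values between 1 and 6), moved the count of 42 to 2 (without WT S5 replicate 1 or 2), 96 (WT S5 replicate 3), 27 (KO S5 replicate 3), 11 (WT S7 replicate 2) and 3 (WT S7 replicate 4, KO S7 replicate 2 or 3), and ended the calls of ASIC2 (adjusted p up to 0.0628), OAS1 (0.0949) and MYT1 (0.0949).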

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

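The results below had a KO effect that differed between stages by a test of the difference itself. Groups of 3 libraries are too small to be searched for outlying libraries. The camera tests of the differences between stages, the tests of the share of endocrine cells and of the share of alpha, delta, gamma and epsilon cells, and the tests of a single library were chosen only after the results were seen.

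OAS3 and OAS1, both induced by interferon, were higher in KO at S5, and this effect was smaller later: the log2 KO effect of OAS3 differed by −2.332 between S6 and S5 and by −3.162 between S7 and S5, and that of OAS1 by −2.334 between S7 and S5. A single KO library is argued against, since at S5 the lowest KO library exceeded the highest WT library 3.88-fold for OAS1 and 5.84-fold for OAS3. Besides these 2 genes, 34 other interferon-stimulated genes were looked at, a list that is not among the 22 lists named above. The camera p-values given for this list are not adjusted over lists. At S5 the 34 genes had a median log2 fold change of 0.28 (SE 0.092, 28 of 34 above 0), with IFITM1 called. Camera placed them higher (p = 7e-07, or 0.00174 with an estimated correlation). In these libraries the increase at S5 was thus not confined to OAS1 and OAS3. At S6 their median was 0.327 (camera p = 3.43e-10, or 0.000273 with an estimated correlation), with PARP9 and MX1 called, and at S7 it was −0.067 (camera p = 0.453, or 0.554). The KO effect on them was smaller at S7 than at S5 as a list (median difference −0.302, camera p = 7.72e-07, or 0.00171 with an estimated correlation), with no single member called. An interferon response in the KO cultures stays open, since the median of 0.28 lies between the values set beforehand for and against it. Loss of ZNF808, and any other difference between the KO and WT cells, stay open and untested.

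At S7 the alpha list and the delta, gamma and epsilon list were lower in KO and the enterochromaffin list was higher, and 2 of them differed from S5: the median log2 differences between S7 and S5 were −0.484 (delta, gamma and epsilon) and 0.459 (enterochromaffin), though neither call held with an estimated correlation (adjusted p = 0.0566 each). A single KO or WT library is argued against, since 27 of 27 means of a list in a KO library minus a WT library at S7 had the sign of the pooled difference (the alpha list between −0.33 and −0.016). This does not rest on the tags, which did not pair the S7 libraries and are not said to be separate differentiations. Taken by tag, 9 of 9 means had that sign, but these 9 are among the 27 and add no evidence of their own. As far as the tags mark differentiation experiments, the 27 means argue against a single one as the source. The lists were taken up because camera called them in these same libraries, which favours like signs. A lower share of endocrine cells is not decided. Over members not shared between the 2 sides, 21 secretory granule genes had a mean of 0.054 at S7. This was 0.343 above the mean of −0.289 of 26 alpha, delta, gamma and epsilon genes (SE of the difference 0.122). The SE was taken over genes as if they were independent and leaves out the spread between libraries. The values show only that the granule genes were not lower on average. A lower share of alpha, delta, gamma and epsilon cells as the whole cause is not decided either. Of their 27 markers, 3 rose (BCHE, TM4SF4 and POU3F4, adjusted over the 2 lists alone) where 11 fell. Whether the 3 that rose are made by these cells alone was not tested. A changed state of these cells stays open. An effect of the genotype stays open as well and was not tested beyond the comparison itself.

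AMN differed by −3.8 between S6 and S5 and by −5.723 between S7 and S5 on the log2 scale, with KO effects of −0.11, −3.91 and −5.83 at S5, S6 and S7. AFP differed by −2.1 between S7 and S5. ASIC2 differed by 1.207 and MYT1 by 0.856, both lower in KO at S5. Of the other lists, camera on the difference between S7 and S5 called beta cell (median log2 difference 0.388), endocrine progenitor (0.28), secretory granule (0.206), neural (0.355) and monogenic diabetes and pancreatic agenesis (0.26) upwards. It called pancreatic duct (−0.413), stomach (−0.462), mesenchyme (−0.977) and proliferation (−0.713) downwards. Of the 11 lists, that of monogenic diabetes held with an estimated correlation (adjusted p = 0.0173), and the other 10, enterochromaffin and delta, gamma and epsilon cells included, did not (adjusted p between 0.0566 and 0.118).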

How the results depend on the processing

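Leaving out experiment E44 and camera on the interaction contrasts were chosen only after the data were seen. All other alternatives were planned and all were run. Of 176 values of the counts of genes, overlaps and lists under settings that keep all libraries or leave out E44, 121 stayed within 1.5 times the reported count, and of 168 values with 1 library left out, 126 did. None of the named genes and lists that passed the test reversed direction under a setting run. Both scaling alternatives kept all 43 list calls and their directions. Where a count moved, the cause was not tested, except that glmTreat asks for a larger change. Without the filter on low counts, the interaction counts were 17 (S6 minus S5), 1 (S7 minus S6), 115 (S7 minus S5) and 77 (joint test).

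DESeq2 called 616 genes at S5 and 424 at S7, and 43 (S6 minus S5), 2 (S7 minus S6), 248 (S7 minus S5) and 184 (joint) for the interaction. On simulated data (KO against WT at S5) 13.1% of its calls were false, against 2.3% for edgeR. The simulation used dispersions that edgeR estimated and had no effect of the tag, so it does not show which count is nearer the truth here. limma-voom called 3 (S6 minus S5), 22 (S7 minus S5) and 1 (joint), and library totals 2 (joint). The replicate block within stage called 1402, 501 and 751 genes at S5, S6 and S7 (351, 193 and 250 of the reported calls kept), 123, 4, 697 and 424 for the interaction in the same order, overlaps of 235 (S5 and S6), 300 (S6 and S7), 204 (S5 and S7) and 158 (all 3), and 9 lists at S6. The tag was not borne out as a pairing at S7, where the E38 libraries correlated at 0.035 and the WT one resembled the KO one of E44 most. At S5, where the E38 libraries correlated at 0.216, both resembled a library of E39 most. With this block at S7, GCG (log2 −0.53, adjusted p = 0.0143), SST (−0.54, 0.00883), PDX1 (0.35, 0.00961), NKX6-1 (0.3, 0.024), CDX2 (1.13, 0.0223), CDH17 (1.08, 0.0101), CRH (−1.12, 7.5e-05), CENPF (−0.58, 0.0333), MCM3 (−0.52, 0.00993) and UBE2C (−0.69, 0.0152) gained a call. A block over all libraries called 8 (S6 minus S5), 108 (S7 minus S5) and 44 (joint). Fitting only the groups compared called 72 at S5, 0 (S6 minus S5; 5 with all groups), 1 (S7 minus S6) and 7 (S7 minus S5), with overlaps of 54 (S5 and S6), 44 (S5 and S7) and 44 (all 3). Against a 1.5-fold change, glmTreat called 55, 55 and 67 at S5, S6 and S7, 5161 and 2604 for the WT contrasts, 1 (S6 minus S5) and 2 (S7 minus S5), with overlaps of 35 (S5 and S6), 46 (S6 and S7), 35 (S5 and S7) and 33 (all 3). Without E44 the counts were 351, 152 and 183 at S5, S6 and S7 (251, 125 and 154 of the reported calls kept), 10008 and 7079 for WT, and 4, 0, 52 and 4 for the interaction.

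With an estimated correlation 0, 2 and 4 lists were called at S5, S6 and S7, and 6 and 3 for the WT contrasts. Fry called 8, 3 and 5 lists at S5, S6 and S7, and 17 for each WT contrast. Of 223 values of named genes, DESeq2 added 12 calls and ended 0, fitting only the groups compared ended 21 and added 5, and library totals ended 8 and added 1.

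With 1 library left out, the counts ran from 153 to 541 at S5, 110 to 157 at S6 and 143 to 203 at S7, from 9438 to 9880 and from 6366 to 7165 for WT, from 1 to 6 (S6 minus S5), 0 to 0 (S7 minus S6), 2 to 96 (S7 minus S5) and 2 to 15 (joint). Overlaps ran from 74 to 114 (S5 and S6), 85 to 114 (S6 and S7), 76 to 97 (S5 and S7) and 62 to 88 (all 3), and lists from 5 to 14 at S5, 4 to 6 at S6, 6 to 9 at S7, 11 to 12 and 9 to 11 for WT. The count between S6 and S5 was 1 without WT S5 replicate 1, KO S5 replicate 3, WT S6 replicate 2 or KO S6 replicate 1, 2 without WT S5 replicate 3 or KO S6 replicate 3, and 3 without WT S5 replicate 2, KO S5 replicate 2 or WT S6 replicate 1. The joint count was 2 without WT S6 replicate 2 or KO S6 replicate 1, 3 without WT S5 replicate 1 or 2, KO S5 replicate 3, WT S6 replicate 1 or WT S7 replicate 2, 8 without WT S7 replicate 3 or KO S7 replicate 4, and 9, 15, 10 and 11 without WT S5 replicate 3, KO S5 replicate 1, KO S5 replicate 2 and WT S6 replicate 3. Among lists at S5, duct also lost its call without WT replicate 1 (adjusted p = 0.144), pluripotency without WT replicate 2 (0.0771) and endocrine progenitors without WT replicate 3 (0.0778).

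Signs reversed for values that did not pass the test in the reported fit either. INS at S5 was 0.068 without WT replicate 2 and 0.107 without KO replicate 3. AFP at S6 was −0.248, −0.174 and −0.011 without WT replicate 3, KO replicate 1 and KO replicate 2, and −0.049 without E44, and at most 0.224 (without KO replicate 3). ALB at S7 was −0.08, −0.052 and −0.388 without WT replicates 2 and 4 and KO replicate 3, and at most 0.483 (without WT replicate 3). ALB in WT S6 against S5 was −0.022 without WT S5 replicate 2 and at most 0.438 (without WT S5 replicate 1).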

Other observations

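The tests of histone genes, of zinc finger genes, of protocadherin, imprinted and X-linked genes, of the run of genes on chromosome 1, of the course of differentiation on its own step, and the draws that keep the pairs, were chosen only after the results were seen.

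Transcripts of replication-dependent histone genes were higher in KO. Of 34 tested, H4C8, H2AC6, H2AC20 and H1-2 rose at S5, 14 rose at S6 and 17 at S7, and none fell. Their median log2 fold change was 0.297, 0.893 and 1.058 at the 3 stages, and at S7 the linker histone gene H1-2 stood at 286 ± 16.5 CPM in KO and 99.8 ± 17.9 CPM in WT (SD, n = 3 each). Most such transcripts lack a poly(A) tail, and the libraries were made from polyadenylated RNA, so the levels need not follow the whole pool of histone RNA. Camera placed the histone list higher at S7 (p = 7.32e-56, or 2.7e-07 with an estimated correlation). The proliferation list had 0 of 24 members above 0 at S7 and none called, and its lower placing (adjusted p = 1.05e-07) did not hold with an estimated correlation (0.399). At S6 the median of the histone list was 0.909 above that of the proliferation list (−0.016). So at S6 and S7 the values argue against histone transcripts that follow the proliferation list. At S5 both lists were higher by about as much (difference of the medians −0.031, with 24 of 24 proliferation genes above 0, adjusted p = 0.000209, a call that did not hold with an estimated correlation), so there this stays open.

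Among the 89 genes called in the same direction at all 3 stages were 6 clustered protocadherin genes, which code for adhesion molecules and are chosen cell by cell in neurons. PCDHA6 and PCDHB5 were higher, and PCDHA11, PCDHA13, PCDHGA10 and PCDHGB4 were lower. By Fisher's exact test (two-sided) this is more than a random choice of tested genes gives (odds ratio 45.2, 95% interval 15 to 114), though reads shared within the clusters make single members uncertain. The imprinted genes DIRAS3 and MEST were both higher (odds ratio 10.8, 95% interval 1.24 to 42.7, on 2 genes). Of the X-linked genes, ARMCX1, ARX, DYNLT3 and ZXDA were lower and ZNF630 was higher (odds ratio 1.75, 95% interval 0.551 to 4.26).

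For these 89 genes 3 explanations were weighed. Gain or loss of segments that span the 5 tested genes on each side is argued against as the cause for the whole set. These neighbours had a median log2 fold change of 0.016 in the direction of the gene, against 1.594 for the genes themselves. A segment of only a few genes would not move a median over neighbours, so shorter gains or losses stay open. For 6 genes the neighbours moved with them by 0.4 or more. Among these are AL133216.2, BX322639.1, HSD17B7P2 and ZNF37A, all on chromosome 10 and lower in KO. Their neighbours had medians of 0.773, 0.773, 0.601 and 0.63 in the direction of the gene. Genes of 1 chromosome may count among each other's neighbours, so these need not be separate cases. Also among the 6 are ETNK2 (0.416), within the run on chromosome 1, and the histone gene H2AC6 (0.539). An inherited epigenetic state that differs between the KO and WT cells stays open. Of the genes, 13 were protocadherin, imprinted or X-linked where 3.31 would be expected (odds ratio 4.49, 95% interval 2.28 to 8.2). These classes were chosen after the genes were seen, and 6 of the 13 are clustered protocadherins. X-linked genes, 5 of the 13, were not over-represented alone (odds ratio 1.75, 95% interval 0.551 to 4.26). The excess therefore does not decide on this explanation. A difference between 2 cell lines that is unrelated to ZNF808 cannot be told apart from an effect of the knockout, since the labels give 1 KO genotype and no second line or rescue. A direct effect of the loss of ZNF808 stays open and was not tested, as no binding sites or repeat annotation were at hand.

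For the run of 39 genes on chromosome 1 from LAD1 to NUAK2, a copy-number difference of this segment between the KO and WT cells is a hypothesis that stays open. The window and its threshold were picked after windows of 11 and 21 genes had been seen on the mean of the stages, so none of the values below is independent of the choice. With these settings the median over 21 neighbouring genes of at least 5 CPM gives the run from the S5 values. The median of the run was −0.322 in the S6 libraries and −0.365 in the S7 libraries. Of the KO and WT libraries of a tag at S6 and S7, all 6 pairs had a median below 0, between −0.365 and −0.277. On the S5 values, 0 of 1000 permutations of the gene order gave a run as long (the longest held 18 genes; with another seed, used before, a longer one was drawn, and again 0 reached 39). No DNA data were at hand to test the hypothesis.

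A further hypothesis is that zinc finger genes are prone to a lasting difference between the KO and WT cells. Of the 89 genes 8 were zinc finger genes where 2.69 would be expected (odds ratio 3.2, 95% interval 1.33 to 6.65, Fisher's exact test, two-sided, adjusted p = 0.00917), 6 of them higher, which may also reflect reads shared between close relatives.

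Whether KO cells lag behind WT cells at S5, or are ahead of them at S7, is left open here. On the WT change of the other 2 tags from S5 to S6, which shares no library with it, the KO minus WT difference at S5 had slopes of 0.000386, −0.0232 and −0.0261 for E38, E39 and E44 (mean −0.0163, SE 0.00839), where a lag needs negative ones. At S7, on the change from S6 to S7, the slopes were −0.04, −0.00756 and 0.0266 (mean −0.00699, SE 0.0192), where being ahead needs positive ones, and the tags do not pair the S7 libraries. The tests planned first used the other step of the course (1 of 3 slopes negative at S5, 2 of 3 positive at S7). By the rule set beforehand, slopes of mixed sign count against a lag at S5 and against KO cells being ahead at S7. That outcome is not taken to decide either question, since the mean slopes lay within 2 SE of 0 (0.0106, SE 0.006, and 0.0173, SE 0.0111). The comparison with 2 SE was not part of that rule. The 2 steps of the WT course were also only weakly alike across genes (r between 0.128 and 0.159, with no library shared), though 5 of the 6 lists called in both steps kept their direction and only the neural list turned.

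The calls were compared with other splits of the same libraries. For 3 libraries against 3 there are 10 splits, too few to exclude chance. At S5 the real split called 351 genes and 2 of the 10 splits called as many or more, the highest other one 647. That split parts WT replicates 1 and 2 and KO replicate 2 from WT replicate 3 and KO replicates 1 and 3, so it follows experiment E39 on one side and E44 on the other and points to a structure of the samples, and with the tag as a block 1402 genes were called. At S6 the real split called 195 and the highest other one 0, so 1 of 10 splits gave as many. At S7 the values were 252 and 163, with 1 split of 10, and for WT S6 against S5 and S7 against S6 they were 10514 and 0 and 7646 and 0, again with 1 split of 10 each. Where the tags pair the libraries, 4 splits part all 3 pairs, and the other 3 called 0 genes at S5 and at S6. For the joint interaction test, 11 of 100 draws of the genotype labels called at least 5 genes (highest 243). For the difference between S7 and S5, 6 of 100 called at least 42 (highest 150). For that between S6 and S5, 9 of 100 called at least 5 (highest 404). So for these 3 counts chance was not excluded. Of the other draws that called as many in the joint test and between S7 and S5, 1 of 10 and 0 of 5 parted all 3 pairs at S5. Of all 99 other draws 36 did, a difference that was not tested. Labels were also swapped only within pairs at S5 and S6 and drawn freely at S7. Then 10 of 100 draws called at least 5 in the joint test (highest 489) and 8 of 100 at least 42 between S7 and S5 (highest 389). Between S6 and S5, 5 of 100 called at least 5 (highest 342). So chance was not excluded there either. Of these, 6 (joint), 3 (S7 minus S5) and 3 (S6 minus S5) swapped the labels of whole stages against each other. That turns the KO effect itself into a difference between stages. Without such draws, 4 of 94 (joint), 5 of 97 (S7 minus S5) and 2 of 97 (S6 minus S5) were left, the real labels included. This choice was made after the draws were seen.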
